A study of Rattus norvegicus with 6 samples.

How the data were processed

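Circular RNAs (circRNAs), closed RNA molecules recognised by reads across a back-splice junction, were measured in dental follicle cells of the rat, the connective tissue cells around the developing tooth. Per the labels' protocols, the cells came from tooth germs of rats 5 to 7 days old and were kept for 28 days either in control medium with 5% serum or in the same medium with 1% of an induction liquid (dexamethasone 0.010 mmol/L, ascorbic acid 0.028 mmol/L, β-glycerophosphate 1.000 mol/L). The labels name 3 control and 3 induction samples. The treatment protocol speaks of 3 rats and the design text of 4, and nothing says whether equal sample numbers mark the same rat. Per the labels' protocols, DNA and linear RNA were removed from total RNA before Illumina sequencing.

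FastQC and BWA, without versions, and the genome build Rnor_6.0 are named per the submitters' processing notes. The circRNA caller, its filters and the removal of duplicate reads are not given in the sources used here. The deposited table held 4143 circRNAs with coordinates on Rnor_6.0 and host gene names. Per the file headers, it gave 1 count column per group, not 1 per sample. How the 3 libraries of a group became 1 column is not given in the sources used here, so the counts may be sums, means or something else. Each deposited count was a whole number of at least 1 in both columns, so a circRNA seen in 1 group only was not analysed here. The deposited TPM values, per the file headers, equalled the count divided by a total and multiplied by 1000000, without correction for length. That total was 203283 for control and 221596 for induction, and the listed counts came to 67.8% and 74.3% of it. The authors' deposited log2 ratio was that of induction TPM over control TPM. The deposited p-value of each of the 4143 circRNAs equalled, within 0.1%, 2 times the smaller tail of the Audic-Claverie read-sampling test on the 2 counts, as recomputed here. The deposited FDR values matched an adjustment over 12390 tests, of which 8247 were not analysed here. These p-values compare 2 columns of reads, not the conditions, and carry no spread between rats.

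With 1 column per group there was no replicate error. The tests chosen before the data were examined (edgeR's quasi-likelihood test across 6 libraries, camera for gene lists, permutation tests of totals and of detection per library) could not be made, and no p-value of the present work is given. In their place, the ratio of induction to control was taken per circRNA on the totals behind the TPM values, with an exact 95% interval (Clopper-Pearson, on the split of the counts between the columns). A circRNA is called 2-fold higher or lower in induction where the ratio was at least 2 either way and this interval excluded equal levels. These intervals cover counting error only. They contain neither the variation between rats nor duplicate reads. The rule was applied to simulated counts for the 4143 circRNAs of the induction against control comparison, with 200 changed. It called 1.67% of unchanged circRNAs, 57.0% of those changed 3-fold and 88.0% of those changed 6-fold. With an added coefficient of variation of 40% per column, it called 15.7% of the unchanged ones.

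Each circRNA was given a host gene. Names that occurred on more than 1 chromosome or over more than 5 Mb of a chromosome (60 names, among them small RNA families) were dropped, and the host was the only name left. This gave 3703 circRNAs a host among 1964 genes. Another 419 circRNAs carried spread names alone, 15 carried several names and 6 had no name. Of the 1964 host names, 1918 matched the RefSeq gene table of assembly GRCr8, which was used for names only (1816 by symbol, 89 by an older symbol, 13 by gene identifier). Of the unmatched names, 5 looked like dates. No annotation of Rnor_6.0 was used here, so exons and introns were not assigned, and strand and exon content of the circRNAs are not given.

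Before the data were examined, 16 host gene lists were fixed: osteoblast differentiation and bone matrix, BMP and TGF-beta signalling, Wnt signalling, collagens and extracellular matrix, glucocorticoid response, adipocyte differentiation, MAPK signalling, focal adhesion and actin cytoskeleton, cell cycle and DNA replication, chromatin modifiers, widely described circRNA hosts, regulators of circRNA formation, and markers of epithelial, leukocyte, endothelial, and muscle or nerve cells. For the 11 lists with at least 5 circRNAs, the median log2 ratio was placed among 10000 random lists of the same size matched on decile of mean TPM. A list is said to stand apart outside the 2.5 to 97.5 percentiles. In simulations, 5 of 100 random lists of 25 circRNAs fell outside this range. The simulated circRNAs were independent and the lists were drawn at random, so this does not check lists in which many circRNAs share a host.

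The circRNAs named were set by a rule fixed before the data were examined. They are the 10 largest ratios in each direction past an adjusted p of 0.05, the 5 of highest mean level, up to 4 of lowest p in each list with at least 5 circRNAs, hosts with at least 3 circRNAs that passed 0.05 in both directions or at least 3 times in 1 direction, and the authors' 5 largest in each direction. The FDR and p of the authors' deposited table stood in for the tests that could not be made, and the rule's condition on single libraries could not be applied. Other names are said to have been chosen after their values were seen. Some host genes that met these rules are not reported here.

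Other scalings (edgeR 4.0.16 TMM factors, DESeq2 1.42.0 size factors, and totals of the listed counts), edgeR's filterByExpr, other thresholds and sums over host genes were tried. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.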

Results

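CircRNAs were compared between dental follicle cells cultured for 28 days with osteogenic induction medium and cells cultured in control medium, to find which circRNAs differ during osteogenic differentiation. The labels name 3 samples per group, but the values were 1 pooled column per group, with no replicates. The listed counts summed to 137740 in control and 164746 in induction over 4143 circRNAs, a ratio of 1.20. The median circRNA had 9 counts in each column, and 51.5% had under 20 counts in both columns together. The differences below therefore have no replicate check, and their intervals are 95% counting intervals. Unless a sum is named, counts and ratios given with a gene are those of a single circRNA, not of all circRNAs of the gene.

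At a difference of 2-fold beyond counting error, 382 circRNAs were higher and 385 were lower in induction, 18.5% of the 4143. In simulated counts with an added coefficient of variation of 40% per column, the same rule called 15.7% of unchanged circRNAs. The variation between the libraries is not known, so how many of the 18.5% reflect induction cannot be told. Summed over the host gene, circRNAs of tenascin N, type XII collagen and the type VI collagen gene Col6a1 were over 2-fold higher in induction, and those of elastin and of the transmembrane protein Crim1 were over 2-fold lower. All 5 circRNAs of Tnn (tenascin N, a matrix glycoprotein) were higher, and their summed counts were 156 in control and 3133 in induction, 18.4-fold higher (15.7 to 21.8). The most abundant of them, on chromosome 13 from 77861167 to 77863480 (Rnor_6.0), had 73 and 2642 counts, a 33.2-fold difference (26.3 to 42.5). The Tnn circRNAs from 77861167 to 77861430, from 77863217 to 77863480 and from 77869300 to 77869563 each spanned 264 nt. The most abundant one begins where the first of these begins and ends where the second ends. Whether reads were misplaced between repeated stretches of Tnn was not tested. Of the 5 circRNAs of Col12a1, a collagen that associates with fibrils, 4 were higher, and their sum was 6.43-fold higher (5.16 to 8.10). All 3 circRNAs of Eln, which encodes elastin, were lower, with sums of 257 and 46 counts, 6.09-fold lower in induction (4.44 to 8.53). Crim1 had 5 of 7 circRNAs lower, with sums of 275 and 96 counts, 3.12-fold lower.

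**Figure D1:**
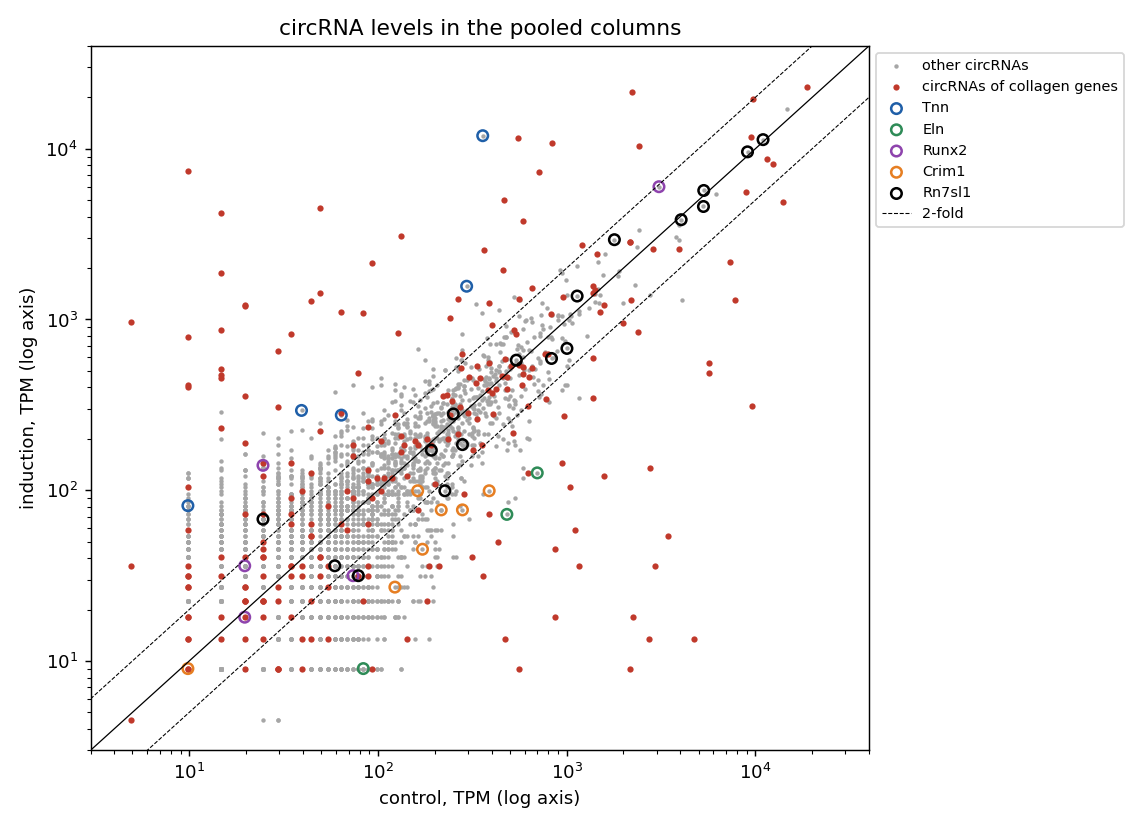
TPM of each of the 4143 circRNAs in the pooled control column (x, log axis) and the pooled induction column (y, log axis), with the line of equal levels and 2-fold lines. Circles mark 5 host genes, and the circRNAs of collagen genes (red) lie on both sides of the lines, with 62 higher and 46 lower.

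The list of collagens and extracellular matrix was the only list of 11 whose median stood apart. The percentiles were not adjusted for the 11 lists, and in simulations 5 of 100 random lists fell outside the range. Of its 301 circRNAs from 37 host genes, 72 were higher, 53 were lower and 176 were neither. Its median log2 ratio of 0.20 lay at percentile 99.1 of random lists, and the share that differed 2-fold was 41.5% against a median of 23.3% in random lists. Without collagen hosts, 12 of its 56 circRNAs were higher and 7 were lower, and the median of 0.33 lay at percentile 98.3. Few hosts gave many of these calls. Adamts6 had 14 of the 56 circRNAs, 3 of them higher. All 5 of Tnn were higher and all 3 of Eln were lower. Among host sums chosen after their values were seen, Serpinh1, the chaperone of procollagen, had 141 and 66 counts, 2.33-fold lower (1.73 to 3.17), and Hspg2, which encodes perlecan, had 6 and 27 counts. With 1 circRNA per host the list's 37 members had a median of 0.29 at percentile 89.4. With sums over hosts the median was 0.20 at percentile 75.8, so the call did not hold at the level of hosts. The median was not smaller, and there were fewer members. Random lists drew circRNAs singly, whatever their host, so the call on 301 circRNAs treats those of 1 host as independent. The same holds for the calls without collagen hosts and without Col1a1 and Col3a1. Fewer members and shared hosts cannot be told apart as the reason. The share that differed 2-fold stayed at percentiles 100 and 99.9 under these alternatives. Without Col1a1 and Col3a1 the list stood apart, with a median of 0.29 at percentile 99.8.

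Within the collagens, circRNAs of the same gene were higher and lower side by side. Collagen genes hosted 247 circRNAs from 17 genes and took 32.7% of listed counts in control (exact 95% interval 32.5 to 33.0) and 35.4% in induction (35.1 to 35.6). Of the 58 circRNAs of Col1a1, the main chain of bone collagen, 18 were higher and 16 lower, and the summed counts were 16421 and 20349, a ratio of 1.14 (1.11 to 1.16). Of the 73 circRNAs of Col3a1, 14 were higher and 14 lower, with sums of 22700 and 28461, a ratio of 1.15 (1.13 to 1.17). Col6a1 had 7 higher and 2 lower of 14, and its sum was 3.59-fold higher (3.30 to 3.91). Col6a2 had 3 higher and 5 lower of 18, and Col11a1 had 3 higher and 1 lower of 14. The sum of Col5a1 was 1.47-fold lower in induction (1.36 to 1.59). The sums of Col1a1, Col3a1, Col6a1 and Col5a1 kept their direction under each scaling tried. Scaling to listed totals moves each log2 ratio by −0.13, which takes away most of the 0.18 of Col1a1 and the 0.20 of Col3a1. In all, 43.7% of collagen circRNAs differed 2-fold, against 16.9% of the 3896 others.

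**Figure D2:**
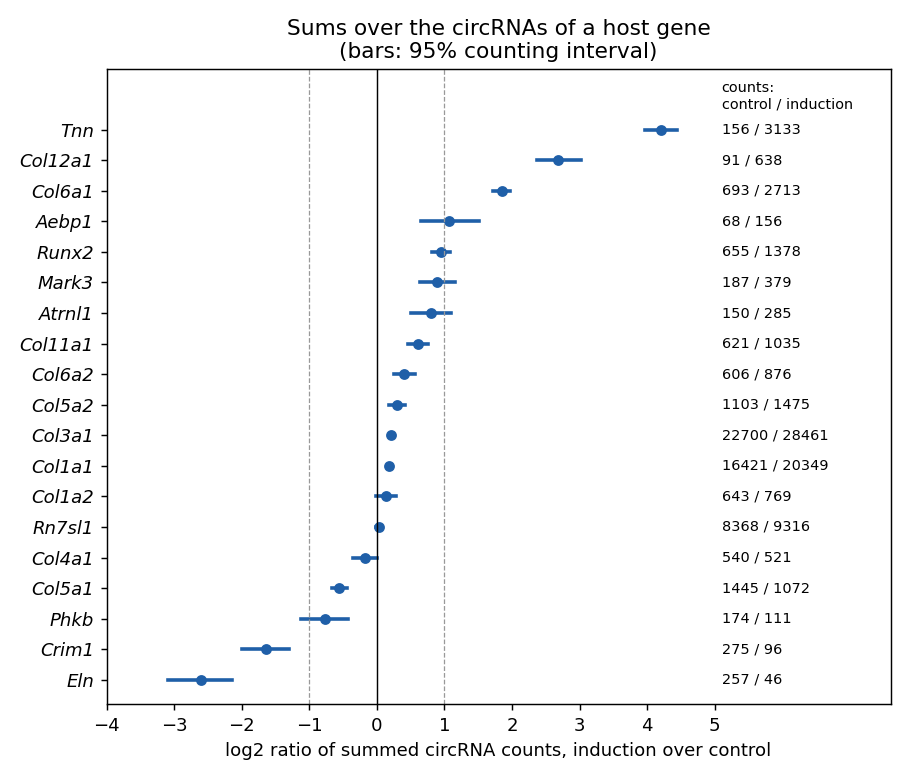
Log2 ratio of the summed counts of all circRNAs of a host gene, induction over control (points), with 95% counting intervals (bars) and dashed lines at 2-fold. Tnn, at 156 and 3133 counts, lies highest and Eln, at 257 and 46, lowest, while Col1a1 and Col3a1 lie near 0.

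The 10 largest ratios in each direction all belonged to collagen genes. The largest was a Col1a1 circRNA on chromosome 10 from 82750961 to 82751318, with 2 counts in control and 1643 in induction, a ratio of 754 (208 to 6228). Another Col1a1 circRNA, from 82749573 to 82753386, had 962 and 3 counts, 350-fold lower (119 to 1698). A Col3a1 circRNA on chromosome 9 from 52041078 to 52042934 had 3 and 929 counts, and another from 52044251 to 52044755 had 440 and 2. The Col5a1 circRNA on chromosome 3 from 6519248 to 6524350 had 594 and 8 counts, 80.9-fold lower. The Col6a1 circRNA on chromosome 20 from 12666784 to 12669319 had 3 and 417 counts, and that of Col11a1 on chromosome 2 from 216965440 to 216967625 had 4 and 269. Most of these ratios rest on fewer than 5 counts in 1 column. Reads between repeated exons of these genes may be placed at several junctions, and each single collagen circRNA is uncertain in that respect.

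**Figure D3:**
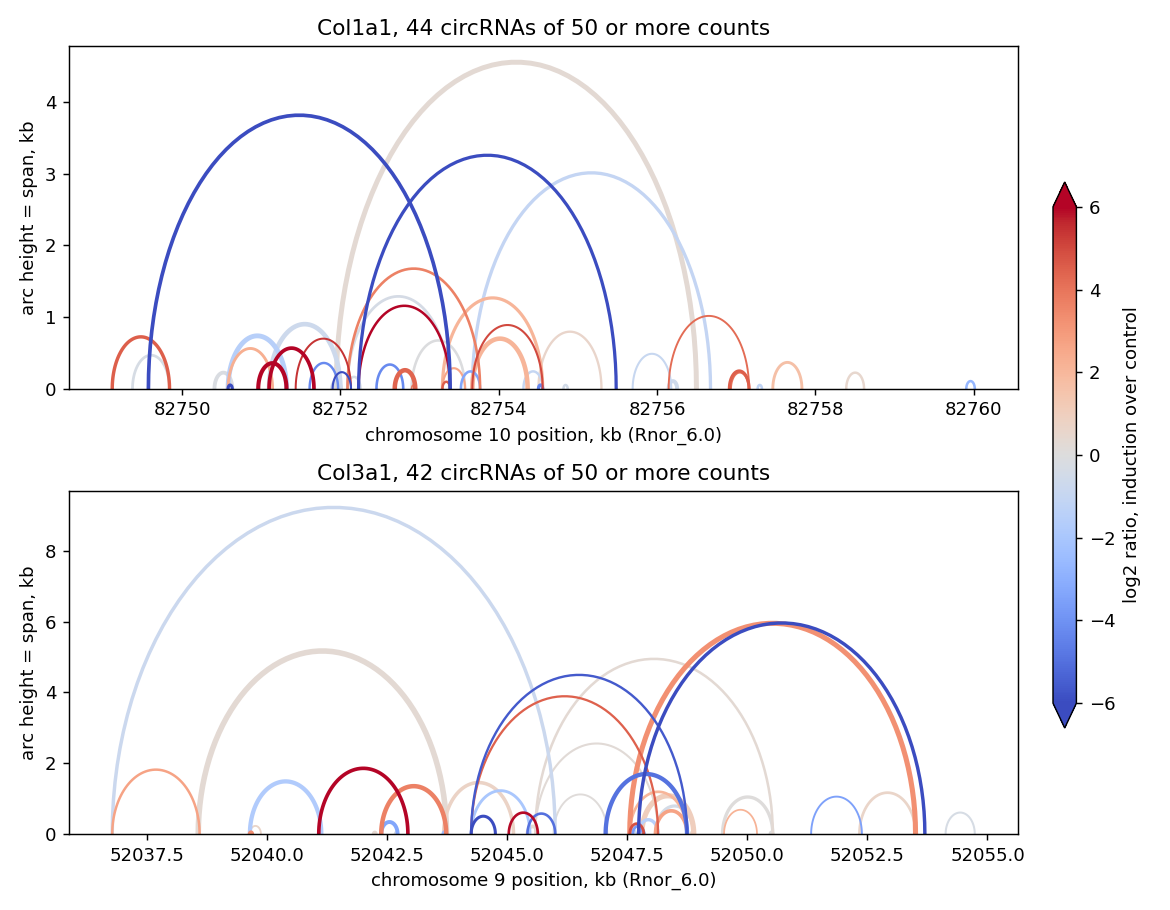
CircRNAs of at least 50 counts on Col1a1 (44, upper panel) and Col3a1 (42, lower panel), each drawn as an arc from start to end (x, kb on Rnor_6.0) with its height equal to its span and its line width growing with its counts. The colour is the log2 ratio of induction over control, and red (higher) and blue (lower) arcs overlap on both genes.

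Of the 22 circRNAs of the osteoblast and bone matrix list, 1 was higher, none was lower and 21 were neither, and the median of 0.19 lay at percentile 72.1 of random lists. The share that differed 2-fold, 4.55%, lay at percentile 1.72 of random lists, whose median share was 22.7%, and between percentiles 2.14 and 6.88 under the alternatives. This share is a second measure, not the rule for standing apart, and was not adjusted for the 11 lists. Other lists also reached extreme shares. With sums over hosts, chromatin modifiers lay at percentile 99.1 (82.4 as reported) and focal adhesion and actin cytoskeleton at 98.0 (73.4 as reported). The list's 9 hosts included Runx2, the transcription factor required for osteoblast formation. Its most abundant circRNA, on chromosome 9 from 18653895 to 18660843, had 627 and 1328 counts, a ratio of 1.94 (1.77 to 2.14), just short of 2-fold, and it passed 2-fold with DESeq2 size factors (log2 ratio 1.01). A second Runx2 circRNA, from 18643596 to 18660843, had 5 and 31 counts and was the list's only call. Another Runx2 circRNA, from 18718032 to 18737731, had 15 and 7 counts and did not differ beyond counting error. The list's counts together were 1142 and 1888, a ratio of 1.52 (1.41 to 1.63), and without the most abundant Runx2 circRNA they were 515 and 560, a ratio of 0.998 (0.883 to 1.13). Cdh11, the osteoblast cadherin, had 139 and 114 counts in its circRNA of lowest p, a difference of less than 2-fold.

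In BMP and TGF-beta signalling, 1 of 26 circRNAs was higher, 2 were lower and 23 were neither (median −0.28, percentile 10.9). The circRNA of Tgfbr2, a TGF-beta receptor, had 93 and 44 counts, 2.30-fold lower in induction (1.59 to 3.38). Ltbp1, which holds latent TGF-beta in the matrix, had a circRNA 2.12-fold higher (187 and 433 counts) and another 3.03-fold lower (125 and 45 counts), and the first fell short of 2-fold when scaled to listed totals (log2 ratio 0.95). The Acvr1 circRNA had 64 and 48 counts. In Wnt signalling, 1 of 15 was higher, 2 were lower and 12 were neither (median 0.03, percentile 48.4). Tcf4, a basic helix-loop-helix factor that shares its symbol with an older name of the Wnt effector Tcf7l2, had 1 higher (2 and 15 counts) and 1 lower (12 and 2 counts). Apart from Tcf4, the list's only call was the lower circRNA of Vangl1, with 13 and 3 counts. Ctnnb1, which encodes β-catenin, had 34 and 20 counts, a difference of less than 2-fold that passed 2-fold when scaled to listed totals (log2 ratio −1.02). In MAPK signalling, 5 of 46 were higher, 3 were lower and 38 were neither (median 0.11, percentile 62.9). The circRNAs of Fgfr2, a fibroblast growth factor receptor, of the kinase Map2k4 and of Rasa2 were 5.73-fold, 5.50-fold and 2.31-fold higher, and that of the kinase Rps6ka5 was 2.43-fold lower. None of these 3 medians stood apart.

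In focal adhesion and actin cytoskeleton, 5 of 83 circRNAs were higher, 10 were lower and 68 were neither (median −0.12, percentile 26.6). Arhgef12 was 8.72-fold lower (40 and 5 counts) and the formin Diaph3 was 4.63-fold lower (51 and 12), while a Ppp1r12a circRNA was 3.47-fold higher. Of 19 Arhgap10 circRNAs, 2 were higher, among them 1 with 13 and 49 counts, and 1 was lower, with 13 and 3, and their sum had a ratio of 1.31. Of 77 circRNAs of chromatin modifiers, 11 were higher, 4 were lower and 62 were neither (median −0.08, percentile 53.2). The circRNA of the histone methyltransferase Ezh2 was 7.63-fold lower (28 and 4 counts), and those of the demethylase Kdm1a (2 and 28) and of Tet3 (5 and 30) were higher. The abundant Hdac4 circRNA had 403 and 276 counts, 1.59-fold lower (1.36 to 1.86), which is less than 2-fold. Cell cycle and DNA replication hosts had 2 of 24 higher, 1 lower and 21 neither (median 0.07, percentile 70.0), with Rb1 at 2 and 26 counts, Cdk17 at 18 and 5, a Cdk14 circRNA at 3 and 17, and another at 8 and 2, which did not differ beyond counting error. Of 6 circRNAs of adipocyte hosts, that of Insr was 2.16-fold higher, that of the desaturase Scd2 was 3.19-fold lower and 4 were neither (median −0.52, percentile 12.8). When scaled to listed totals, Insr fell short of 2-fold (log2 ratio 0.98), and Acaca, an acetyl-CoA carboxylase with 57 and 33 counts, passed it (log2 ratio −1.05 in place of −0.91).

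Regulators of circRNA formation hosted 10 circRNAs, of which those of 2 splicing factors differed 2-fold. Mbnl1 was higher (2 and 21 counts), Rbfox2 was 3.30-fold lower (115 and 38 counts; 2.27 to 4.89), and Hnrnpm had 51 and 86 counts (list median 0.33, percentile 81.9). Of 108 circRNAs of widely described circRNA hosts, 9 were higher, 7 were lower and 92 were neither (median −0.12, percentile 14.5). Zmym4 was higher (4 and 36 counts), and Fat1 (40 and 6) and Afap1 (53 and 9) were lower. The circRNA of Nfix, among the 5 most abundant, had 2977 and 3782 counts, a ratio of 1.17 (1.11 to 1.22).

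**Figure D4:**
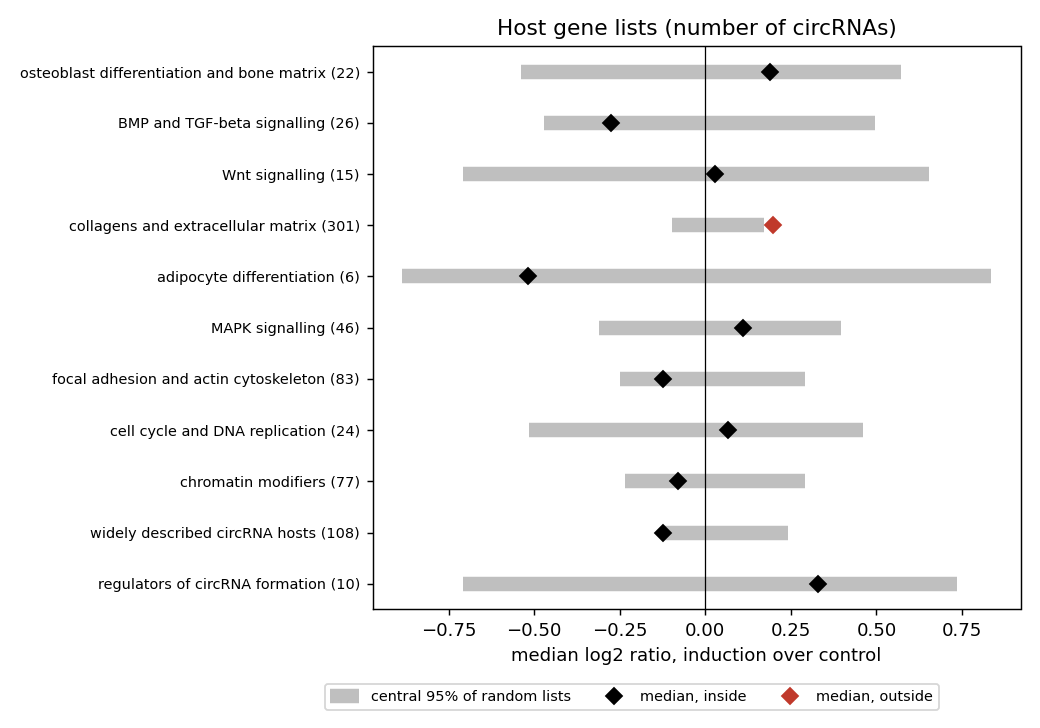
Median log2 ratio (x) of the circRNAs of each of 11 host gene lists (diamonds) with the central 95% of 10000 random lists matched on mean TPM (grey bars), and the number of circRNAs in brackets. The median of collagens and extracellular matrix, 0.20, lies outside its bar, that of widely described circRNA hosts lies on the lower end of its bar, and the other 9 lie inside theirs. That lower end, −0.12, is the value of every circRNA with equal counts in both columns. Many random lists tie there, and the list of widely described hosts lies at percentile 14.5.

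The remaining lists had fewer than 5 circRNAs each. In the glucocorticoid response list, Nr3c1, the glucocorticoid receptor, had sums of 13 and 24 counts over 2 circRNAs, Per1 had 8 and 3 and Ankrd44 had 2 and 5, and none of the 4 differed 2-fold beyond counting error. Of markers of other cell types, no circRNA of an epithelial marker was listed. The leukocyte marker Dock8 had sums of 29 and 19 counts over 2 circRNAs, 1 of them lower, the endothelial marker Flt1 had 48 and 50, and the muscle marker Dmd had 10 and 15.

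Several other hosts had circRNAs that differed in the same direction. Mark3, a microtubule-affinity kinase, had 4 of 6 higher, with sums of 187 and 379 counts, and Atrnl1 had 3 of 10 higher, with 150 and 285. Phkb, a subunit of phosphorylase kinase, had 2 of 8 lower. Opposite directions also occurred outside the collagens. Aebp1 had 1 higher (33 and 149 counts) and 1 lower (33 and 5 counts), and Bcl11b had 1 of each among 3. Those of Bcl11b both start at 131912740 on chromosome 6. The higher one ends at 131913102 (5 and 30 counts) and the lower one at 131913105 (50 and 24 counts). Whether reads were shifted between these close ends was not tested. Among the 5 most abundant circRNAs were 3 of Col3a1. That from 52047552 to 52053503 had 449 and 4734 counts, 9.67-fold higher (8.78 to 10.7), and that from 52038569 to 52043738 had 3798 and 5096, a ratio of 1.23. The fifth lay at Rn7sl1, the 7SL RNA of the signal recognition particle, on chromosome 6 from 91457048 to 91680351, with 2233 and 2505 counts, and the reads there can be shared between near-identical copies.

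In the authors' deposited table, 701 circRNAs had an FDR under 0.05, 360 of them higher and 341 lower in induction. The authors' deposited table put 583 of these at 2-fold or more, and 582 were also called here. Both rules use the same 2 counts per circRNA, so this overlap does not support either. Of the 767 called here, only these 582 also had an FDR under 0.05. The rule used here was not adjusted for the number of circRNAs. With an assumed coefficient of variation of 40% in each column, an alternative chosen after seeing the data, 278 circRNAs met the rule in place of 767, 124 higher and 154 lower, so the counts above describe these columns and not a spread between rats.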

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

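The assumed variation, the 4-fold threshold, the sets without collagens, the host rule of 1 name and the totals without collagens and Rn7sl1 were chosen after seeing the data. No paired analysis was possible because each group had 1 pooled column that carries no sample number. For the same reason the planned DESeq2 and voom tests, filters per library, pseudocounts, thinning, detection per library, camera, fry and leaving out single libraries were not run. The 767 differing circRNAs of 4143, 382 higher and 385 lower, became 772 with TMM, 786 with DESeq2 size factors and 789 with listed totals. With filterByExpr they were 713 of 2308 circRNAs. An unadjusted p under 0.05 in the authors' deposited table, with 2-fold, gave 862. Its FDR under 0.05 and under 0.1 gave 701 and 878, without a 2-fold condition, so these 2 counts are not like the others. The differing circRNAs were 659 of 3896 without collagen hosts and 778 with totals lacking collagens and Rn7sl1. Counted by host gene sums they were 338 (153 higher, 185 lower), of 1964 genes instead of 4143 circRNAs. An assumed coefficient of variation of 40% left 278 (124 higher, 154 lower) and a 4-fold threshold left 370 (170 higher, 200 lower), both by construction stricter. Scaling to listed totals moved each log2 ratio by −0.13, and 327 were then higher and 462 lower. Without the 10 circRNAs of highest mean level the ratio of listed counts was 1.17 in place of 1.20. With 1 circRNA per host 0 lists stood apart, and with sums over hosts 0 did, in place of 1. The matrix list then had 37 members in place of 301, with medians of 0.29 and 0.20 against 0.20 as reported. It stood apart without collagen hosts and without Col1a1 and Col3a1, where circRNAs of 1 host were again treated as independent. Of the 67 named circRNAs, 62 kept their side of the 2-fold rule with listed totals, 66 with DESeq2 size factors and 67 with TMM. No named circRNA changed from 2-fold higher to 2-fold lower, but the scalings could not bring this about. Each moves all log2 ratios by 1 constant, −0.01 with TMM, 0.05 with DESeq2 size factors and −0.13 with listed totals. Depth limits the small ratios: in simulated data with at least 50 counts, 19 of 20 circRNAs changed 3-fold were called, against 53 of 93 at all depths.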

Other observations

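All tests in this part were chosen after the results were seen. Outside the hosts named by rule, further genes with at least 200 counts had circRNA sums that differed 2-fold. Csf1, which encodes the macrophage colony-stimulating factor needed for osteoclast formation, had 191 and 86 counts in 1 circRNA, 2.42-fold lower in induction (1.87 to 3.16). Camta1 and the pantothenate kinase Pank1 were also lower, by 2.28-fold and 2.09-fold, as were Serpinh1 and Diaph3. Parp8 (64 and 178 counts), the phospholipase Pld1 (55 and 148) and Irak3, a negative regulator of Toll-like receptor signalling (60 and 155), were 2.55-fold, 2.47-fold and 2.37-fold higher.

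The first pattern weighed was that circRNAs of the same collagen gene were higher and lower in the same comparison. A single change of the whole host with counting error is argued against, since 59.5% of 153 collagen circRNAs with at least 50 counts (51.3 to 67.3) differed 2-fold from the rest of their host, against 23.6% of 518 others. The 153 included 44 of Col1a1 and 42 of Col3a1, and the intervals in this paragraph treat circRNAs of 1 host as independent. Each circRNA is also part of the rest for the others, so a few that differ strongly can raise this share. Greater depth is argued against too, since at 50 to under 500 counts 55.5% of collagen circRNAs differed 2-fold, against 19.9% of others weighted to the same depths. Of 63 collagen circRNAs under 200 nt, 51 spanned a multiple of 9 nt, as exons of the collagen repeat do, against 22 of 130 others, but misplacement within single exons does not account for the whole pattern, since 61.7% of the 115 collagen circRNAs with at least 50 counts and a span of 200 nt or more (52.2 to 70.6) differed 2-fold, against 22.3% of 792 others with at least 50 counts. Reads joined between different repeated exons, a few molecules amplified in 1 library of a pool, and an effect of induction on single back-splice sites stay open, and separate libraries would be needed to tell them from each other.

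The second pattern was that 5 of 17 entries at Rn7sl1 joined separate loci, with spans of 223286 to 223304 nt, and held 78.9% of the gene's 8368 control counts and 81.1% of its 9316 induction counts. Of the 17, 14 had a mirror image in the table, as inverted copies would give. A candidate explanation is that reads of near-identical 7SL copies were placed between copies. Of 9 short entries named only for the same RNA family, on 3 chromosomes, 88.9% (51.8 to 99.7) repeated a span seen at Rn7sl1. Of 172 other short entries, 5.23% did (2.42 to 9.70). The summed ratio was 1.02, and no biological explanation was tested.

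The third pattern was that circRNAs of the same host tended to share a direction outside the collagens. Pairs were made of circRNAs with at least 20 counts in both columns together. Log2 ratios were taken relative to their median and limited to 4 either way. All correlations and shares of pairs given here are weighted so that each host counts equally. Over 954 pairs in 303 hosts the correlation was 0.18, against −0.10 to 0.10 in 1000 random reassignments. The weighted share of pairs on the same side of the median was 58.5%, against 45.1 to 54.5%. CircRNAs are not independent replicates. A back-splice site shared by the pair stays open as a source. Over 556 pairs with no shared end the correlation was 0.14, against −0.12 to 0.11. Their weighted share on the same side was 55.6%, at the random upper limit of 55.6%. Over pairs with no overlap the correlation was 0.15, against −0.14 to 0.14. Their weighted share on the same side was 53.2%, inside 42.7 to 56.0%. A change common to the host's circRNAs stays a hypothesis without a test of its own, since the correlation is the pattern itself, and it is small. In 12 collagen hosts it was 0.11, inside the random range of −0.20 to 0.21, and the difference between these correlations was not tested.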
